A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

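Total RNA of 4 cultures was hybridised on 8 two-colour arrays, each with the sample in Alexa 532 or Alexa 647 and a common NRC-1 reference (grown to an optical density of 0.5 to 0.6) in the other dye, per the labels. Per the labels, 50 mL cultures were grown in 125 mL flasks. The series design states 4 samples run in duplicate as dye flips, so the arrays of a condition are technical repeats of 1 sample. No spread between cultures of 1 condition enters the p-values. The array numbers in the titles set high oxygen light apart from the other conditions, so any array batch and that condition cannot be told apart.

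The deposited scanner tables give the intensity of each spot and its local background in both dyes at 2 scan settings, with no background subtracted, per the file headers. Scanner and image software are not given in the sources used here. The deposited value table holds log10 ratios by the authors. Their scale, centring and direction were unstated and were worked out here by comparison with the scanner values. Once its rows were put in row-by-row slide order, each column followed log10 of Alexa 532 over Alexa 647 of its own array, with a Spearman correlation of 0.52 to 0.94 for the brighter scan and 0.76 to 0.84 for the dimmer scan. With the dimmer scan each column correlated more with its own array than with any other; with the brighter scan this failed for low oxygen light replicate 1 and low oxygen dark replicate 1. The column medians were 0.03, 0.04, 0.04, 0.03, 0.22, 0.05, 0.04 and 0.01 in the order high oxygen light, high oxygen dark, low oxygen light and low oxygen dark, replicate 1 before replicate 2. The authors' normalization and centring stay unknown. The columns of 6 arrays lacked 476 values, and exact zeros were treated as missing; this table was used as an alternative, centred on each column's median and turned by dye.

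Intensities from the brighter scan (spot mean, local background median) were corrected with normexp at an offset of 50, normalized by loess within each array and averaged over the 4 spots of a probe in limma 3.58.1 under R 4.3.3. The grouping of spots into probes was inferred from the layout and held for 133 of 133 named genes. The scan was chosen after the data were seen and with the counts from both scans known: in the dimmer scan the Alexa 647 background was 0 at 17.3% to 99.9% of spots. Control spots were not identified here and stayed in, as did saturated spots. The platform annotation gave 1 symbol to 532 spots, several to 0 and none to 10220; all 133 symbols occur in the reference gene table, which is of another strain of the species (assembly ASM479960v1), so no coordinates are given. Gene symbols are those of the annotation, and other probes are unnamed here.

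Ratios were turned to sample over reference by each array's dyes, and the 2 arrays of a condition were averaged. limma's lmFit and eBayes were fitted to the 4 samples with oxygen and light as additive terms, with Benjamini-Hochberg adjustment at 0.05. The 1 residual degree of freedom left is the light minus dark difference in high oxygen less that in low oxygen. Standard errors and p-values rest on this difference of differences and on the spread that eBayes shares over probes. Probes at least 2-fold changed in both pairs, and the difference of differences, were counted without a test. Of 26 gene lists fixed before the data were examined, 9 had at least 3 named genes and were tested with camera (preset correlation 0.01, against the named genes) and fry. Lists defined by plasmid or product were not matched to genes here and so were not evaluated. Those on gas vesicles, respiration and translation had too few named members. Shared replicate numbers stand for the dye orientation, not for paired cultures. Leaving out 1 array therefore leaves its condition in 1 orientation, with no dye term in the fit, so a dye bias can enter those values. The design, alternatives, lists and naming rule were fixed before the data were examined. The rule named, per comparison, the 10 genes with the largest log2 change in each direction that passed the test with one direction in both pairs and both dye orientations, filled up by size where fewer passed; up to 4 members per list (the 2 highest and 2 lowest) and all phototrophy, gas vesicle, DMSO and arginine genes; kinA2 and ura3; the 5 largest differences of differences in each direction with one sign in both orientations; and the 5 largest and 5 smallest ratios among probes 2-fold from the reference. As none passed the test, all were filled by size.

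The procedure was tested on simulated data with the spread of the real fit and 200 of 2688 probes changed. Errors were drawn as independent and normal, with no dye bias or array effect, so the counts do not give the recovery in the real data. For a log2 change of 1, 178 were recovered for oxygen with 18 false calls, and 141 for light with 7; for a change of 2, 200 and 193 were recovered with 23 and 12 false calls. False calls thus made up 9.18% and 10.3% of the oxygen calls and 4.73% and 5.85% of the light calls in these single draws. They were above the intended 5% in 3 of the 4. For a change of 3 the shares were 4.76% for oxygen and 6.60% for light. Alternatives were the background correction, normalization, source of ratios, intensity filter, dye orientation, spot summary, each array or sample left out, the model and the thresholds, and, added after seeing the data, the dimmer scan, the median of a spot's pixels, lists without pyrF, gdhA1 and gdhA2, phototrophy without bat, and fry, the further lists and the adjustment over a list alone with each array left out and under other processing.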

Results

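Messenger RNA of the halophilic archaeon Halobacterium salinarum NRC-1 was compared between 4 growth conditions in a strain lacking ura3 and kinA2. Cultures were grown in rich medium to mid-log phase at high oxygen (shaking at 210 rpm) or low oxygen (100 rpm), each in light and in dark, so that the comparisons ask how oxygen supply and illumination alter transcript levels in this strain. Each condition was 1 sample, hybridised on 2 arrays with the dyes exchanged, against a common NRC-1 reference, giving 4 samples on 8 arrays. Each array held 10752 spots, read here as 2688 probes of 4 spots, of which 133 carried a gene symbol and 2555 were unnamed. The small number of arrays limits the precision, and no condition had a second culture. The median ratio of spot to local background in the sample's channel ran from 1.08 on high oxygen light replicate 2 to 2.32 on high oxygen dark replicate 2. The spread of log2 ratios over probes was 0.72 (SD) on low oxygen dark replicate 2 and between 0.25 and 0.36 on the other arrays.

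The gene inactivated with kinA2, ura3, encodes orotidine 5'-phosphate decarboxylase and is listed under the symbol pyrF. Its log2 ratio of sample to reference was -0.56 ± 0.25 (SD, n = 4 samples), and it lay below the reference on 7 of the 8 arrays, the array above it being high oxygen light replicate 2 at 0.02. Its signal was near background, with a median spot to background ratio of 1.16 in the sample channel and 1.32 in the reference channel, so the ratio is a weak check of the labels, and which part of the gene the probe covers was not known. The probe for kinA2 was not analysed here because none of the named probes carried that symbol. Across all probes, 1 unnamed probe was at least 2-fold below the reference in all 4 conditions and 0 were at least 2-fold above it; without low oxygen dark replicate 2, 0 probes met this rule.

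The 2 arrays of a condition resembled each other little. Over 2688 probes their log2 ratios, turned to sample over reference, correlated at 0.22 in high oxygen light, 0.20 in high oxygen dark, -0.14 in low oxygen light and -0.21 in low oxygen dark, and the SD of their difference was 0.40, 0.42, 0.49 and 0.81. These are correlations across probes, which are not independent replicates. Arrays of different samples with the same dye orientation correlated at 0.24 on average, against 0.02 for the 2 arrays of a sample. Of the 24 ways of pairing the 4 arrays of one orientation with the 4 of the other, 10 gave a mean correlation at least as high as the true pairing (exact one-sided p = 0.417), so the condition was not detectable in the similarity of the arrays.

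**Figure D1:**
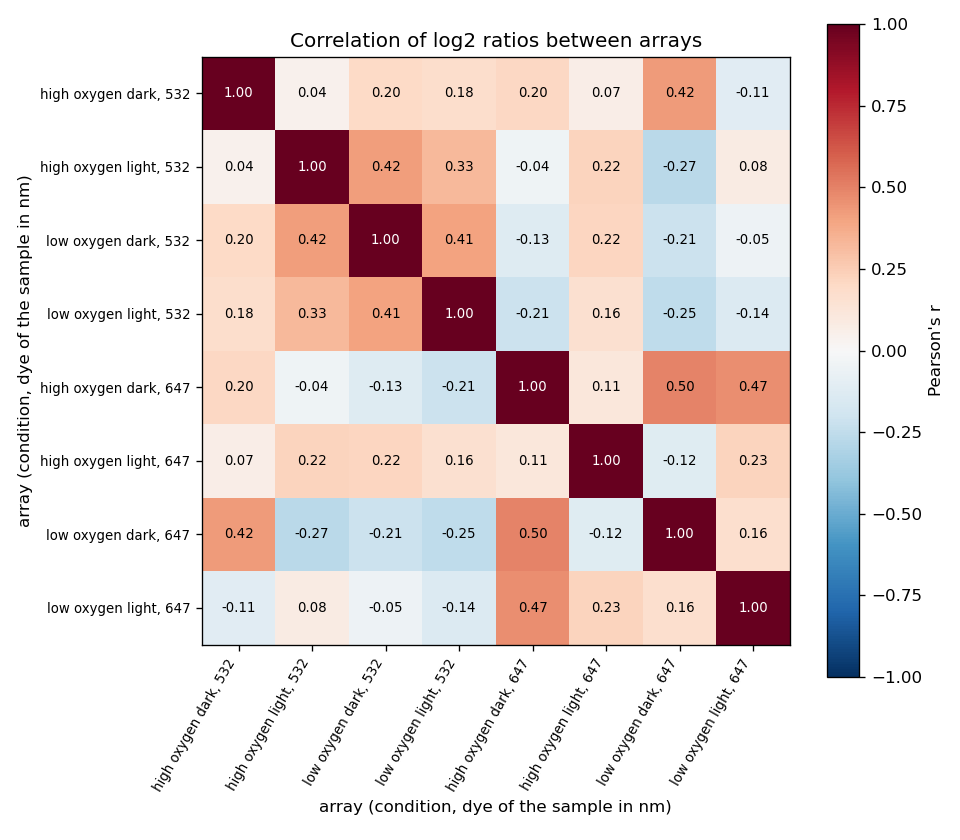
Pearson's r of log2(sample/reference) between each pair of the 8 arrays over 2688 probes, with arrays ordered by the dye of the sample (532 or 647 nm) on both axes. Pairs of the same orientation average 0.24, whereas the 2 arrays of one sample range from -0.21 to 0.22.

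Between high and low oxygen, gdhA1, which encodes a glutamate dehydrogenase, had a log2 difference of 0.36 ± 0.11 (SE, 4 samples), and sucC, encoding a succinyl-CoA synthetase subunit of the citrate cycle, had -0.37 ± 0.11. Both had spots well over background, with sample ratios of 5.74 and 3.01. The transducer genes htr18 and htr4 were at 0.36 and 0.34, and hisD of histidine synthesis at 0.32. Without background correction these 3 were at 0.06, -0.19 and 0.07, and with the authors' values at 0.04, -0.05 and 0.01. At the low end were bat, the activator of bacterio-opsin gene expression, at -0.50, the thymidylate kinase gene tmk at -0.48, glyS at -0.29, uvrA at -0.26, serS at -0.24 and mdh, the malate dehydrogenase gene, at -0.24. Several of these were near background, with sample ratios of 1.03 for htr18, 1.06 for tmk, 1.36 for bat and 1.51 for htr4, and gatC was at 0.98. The remaining genes with the largest differences in one direction in both pairs and both dye orientations were gatC (0.34), hop (0.22), serB (0.14), htr6 (0.14), arcC (0.13) and htr7 (0.12) on the high side and panB (-0.19), nuoL (-0.19) and pheS (-0.18) on the low side. Of the 133 named genes, 14 on the high side and 25 on the low side met this direction rule. A chance share of 0.25 would assume unlinked signs. The pairs and the orientations average to the same value, so their signs are linked and that share does not hold. The count was thus not tested against chance, and meeting the rule is no support by itself. The oxygen differences of the 2 dye orientations correlated at -0.18 over the named genes and -0.30 over all probes. In some genes a single dye orientation carried the difference. With the sample in Alexa 532, bat was at -0.00 and mdh at -0.01, against -0.995 and -0.466 in Alexa 647. In Alexa 647, serS was at -0.03, nuoL at -0.04 and pheS at -0.02, against -0.46, -0.35 and -0.35 in Alexa 532. Of the 20 values, 15 moved by over 1.5 times in Alexa 532 only and 10 in Alexa 647 only. The direction of gatC turned without background correction (-0.76) and with the authors' values (-0.58). With the authors' values mdh was at 0.14 and nuoL at 0.25. In the dimmer scan of the same slides hop was at -0.05, hisD at -0.02, nuoL at 0.03 and tmk at 0.03. Without high oxygen light replicate 2 arcC was at -0.02, and without low oxygen light replicate 1 pheS was at 0.10.

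None of these oxygen differences passed the test. limma called 0 of the 2688 probes at an adjusted p under 0.05, the lowest adjusted p being 0.741, while 170 probes had an unadjusted p under 0.05 against 134.4 expected by chance. Adjusted over the 133 named genes alone the lowest p was 0.679. With each array left out in turn, 19 of the 20 values moved by over 1.5 times at least once, the exception being hisD. Without high oxygen light replicate 2, 10 did: sucC was then at -0.11, mdh at -0.14, nuoL at -0.31, panB at -0.07, pheS at -0.09, hop at 0.11, htr6 at 0.09, serB at 0.05, htr7 at 0.01 and arcC at -0.02. Without low oxygen dark replicate 2, 8 did: bat and uvrA were at -0.02, tmk at -0.18, glyS at -0.13, mdh at -0.15, panB at -0.33, pheS at -0.30 and arcC at 0.23. The gdhA1 value was 0.13 without low oxygen light replicate 2. In both the light pair and the dark pair, 0 probes were at least 2-fold higher and 0 at least 2-fold lower in high oxygen, against 0.0231 lower probes expected if the pairs were unrelated.

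By list, all 6 measured citrate cycle genes were on the low side in high oxygen, from citZ and sdhC at -0.02 to mdh at -0.24 and sucC at -0.37, and 5 of 7 halobacterial transducer genes were on the high side, with htr8 at -0.05 and htr1 at -0.06 lowest. With the authors' values 5 of the 6 citrate cycle genes were on the high side. Neither list passed limma's camera test (adjusted p = 0.107 for both; 0.890 for both with an estimated correlation). limma's fry test for change in one direction, 0.521 for the citrate cycle, called it with scaling between arrays (0.00541) and without high oxygen dark replicate 2 (0.0398). The 6 phototrophy genes, for the sensory rhodopsins, halorhodopsin and their partners, had hop at 0.22, htr2 at 0.00, sop2 at -0.03, htr1 at -0.06, sop1 at -0.07 and bat at -0.50 (adjusted p = 0.727). Adjusted p-values were 0.557 for flagellum and chemotaxis (4 of 4 on the high side, cheR at 0.08 to cheB at 0.03, but 1 of 4 without low oxygen dark replicate 1), 0.557 for chaperones and proteasome (4 of 5, pan1 at 0.10 to dnaK at -0.02), 0.652 for purine and pyrimidine synthesis (6 of 10, purB at 0.33 to purL at -0.11), and 0.816 for DNA repair, cobalamin synthesis, and glycolysis, gluconeogenesis and glycerol. The last list also held the glutamate dehydrogenase genes gdhA1 and gdhA2; without them 1 of its 4 genes was on the high side (adjusted p = 0.552). The DNA repair list had a mean of -0.00 and a median of 0.06. Adjusted over the list alone, 0 genes of any list passed. Both measured genes of arginine fermentation, arcA at 0.06 and arcC at 0.13, were too few for a list test.

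Between light and dark, the named genes furthest on the low side, among those with one direction in both pairs and both dye orientations, were tmk at -0.87 ± 0.15 (SE, 4 samples), the histidine degradation genes hutG at -0.66 ± 0.15 and hutI at -0.55, nadA of NAD synthesis at -0.60, mamA at -0.53, trpB of tryptophan synthesis at -0.50, bat at -0.50, the excision repair gene uvrA at -0.48, menD at -0.47 and gatC at -0.45. On the high side were pyrF, labelled as deleted in every sample, at 0.41, the proteasome-activating ATPase gene pan1 at 0.41, phoU at 0.33, speB at 0.25, the carbamate kinase gene arcC at 0.23, panB, gyrA and thiC at 0.15, purM at 0.14 and glpK at 0.13. The low-side genes were dim, tmk having a spot to background ratio of 1.06 and menD, the brightest of them, 1.86. Their order did not hold under other processing. Without background correction tmk was at -0.23, trpB at -0.03, hutG at -0.09 and gatC at 0.80. With the authors' values tmk was at 0.06, hutG at 0.10, hutI at 0.11, nadA at 0.02, trpB at 0.04 and gatC at 0.57. On the high side pyrF (1.16), pan1 (1.55) and glpK (1.70) were dim too, whereas phoU had 8.58 and arcC 8.40. In Alexa 532 only, 10 of the 20 values moved by over 1.5 times, among them pan1 (0.05, against 0.76 in Alexa 647) and menD (-0.10, against -0.84), and in Alexa 647 only 4 did. With the authors' values gyrA was at -0.01 and thiC at -0.09, and thiC was at -0.02 in the dimmer scan. Of the 133 named genes, 21 on the high side and 31 on the low side met the direction rule for light. As the signs are linked, this count was not tested against chance either.

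**Figure D2:**
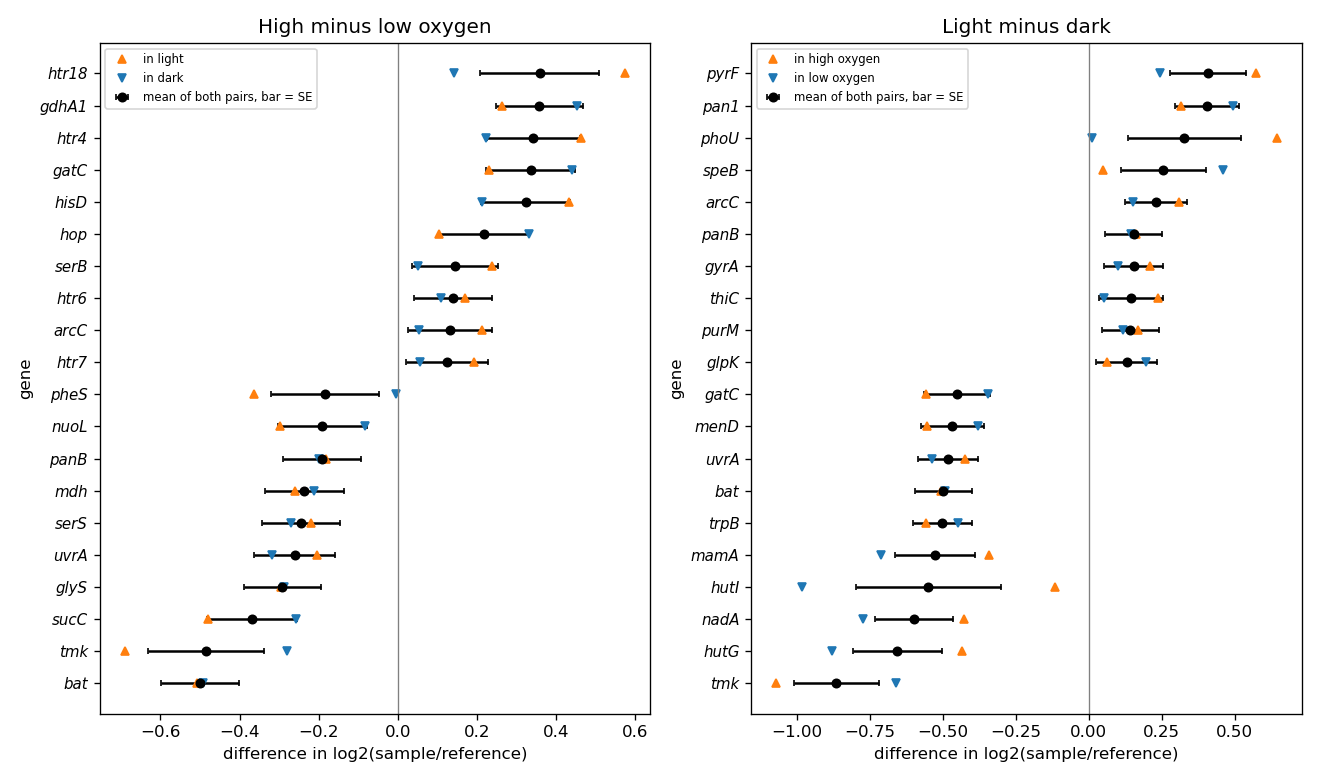
Differences in log2(sample/reference) between high and low oxygen (left) and between light and dark (right) for the 20 genes each rule names, with the mean and SE from the limma fit in black and each pair of samples as a triangle. The values run from -0.50 for bat to 0.36 for htr18 on the left and from -0.87 for tmk to 0.41 for pyrF on the right, and none passed the test.

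limma called 0 probes for light (lowest adjusted p = 0.123), with 594 unadjusted p-values under 0.05 against 134.4 expected. This count changed when single arrays were left out. Without high oxygen light replicate 2, the array with the weakest signal, it was 168 (82 higher and 86 lower in light). Without low oxygen dark replicate 2 it was 4. Each of these fits also leaves 1 condition in a single dye orientation, so the array and a dye bias cannot be told apart. A dimmer scan of the same slides, tried after the data were seen, gave 181 calls, 57 higher and 124 lower. The named genes called were nadA and tmk without high oxygen light replicate 2. They were bat and endA in the dimmer scan, so no named gene was called in both. Of the 20 values, 12 moved by over 1.5 times without low oxygen dark replicate 2: bat was then at -0.02, nadA at -0.11, hutG at -0.24, uvrA at -0.25, tmk at -0.56, pan1 at 0.02, speB at 0.01, panB at 0.01, purM at 0.08, pyrF at 0.25, gyrA at 0.23 and glpK at 0.24. Without high oxygen light replicate 2, 5 did: arcC was then at 0.08, glpK at -0.02, menD at -0.29, panB at 0.27 and pyrF at 0.26. With each array left out in turn, 15 of the 20 moved this far at least once, the others being hutI, mamA, phoU, thiC and trpB.

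In both oxygen levels, 8 probes were at least 2-fold lower in light and 0 at least 2-fold higher, against 0.894 and 0 expected if the pairs were unrelated. All 8 were unnamed and near background (sample ratios of 0.872 to 1.14), and the count was 0 once the dimmest 25% of probes were left out and 0 without low oxygen dark replicate 2. Centring each array on its median in place of loess gave 5 higher and 3 lower.

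No list passed camera for light, the lowest adjusted p being 0.726 (0.908 with an estimated correlation). That value was shared by purine and pyrimidine synthesis (7 of 10 on the high side, or 6 of 9 without the deleted pyrF, and purB lowest at -0.33), chaperones and proteasome (3 of 5), glycolysis, gluconeogenesis and glycerol (3 of 6, or 3 of 4 without gdhA1 and gdhA2), flagellum and chemotaxis (4 of 4, cheY at 0.06, but 0 of 4 with the authors' values), cobalamin synthesis (0 of 4, but 3 of 4 without low oxygen dark replicate 2), transducers (4 of 7, htr8 at 0.18 and htr4 at -0.37) and phototrophy, while the citrate cycle had 0.741 and DNA repair 0.916. With pyrF, gdhA1 and gdhA2 left out, a choice made after the data were seen, the lowest adjusted p was 0.714. Of the phototrophy genes htr2 was at 0.05, hop at 0.02, htr1 at -0.01, sop2 at -0.03, sop1 at -0.09 and bat at -0.50. limma's fry test for change in either direction gave this list an adjusted p of 0.0187, which rested on bat. It was 0.937 without that gene and 0.946 without low oxygen dark replicate 2, where bat was at -0.02. With each array left out in turn it ran from 0.133 to 0.946. With camera and an estimated correlation the list's adjusted p was 0.908. Adjusted over the list alone, 1 gene of the 9 lists passed, uvrA of DNA repair (limma adjusted p = 0.0468). It ran from 0.0301 to 0.992 with each array left out, the highest being without low oxygen dark replicate 2, and was 0.918 with the authors' values. The transducers had a median of 0.05 and a mean of -0.03, and DNA repair a median of 0.04 and a mean of -0.07.

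Among named genes with one sign in both dye orientations, the light minus dark difference of phoU, named after a regulator of phosphate uptake, was 0.65 in high oxygen and 0.01 in low oxygen. That of hutI was -0.12 and -0.98, but its spots were at background (sample ratio 1.04, reference ratio 0.93), as were those of htr18 (1.03 in the sample channel), so their sizes are not well measured. The difference of these differences was 0.87 for hutI, 0.63 for phoU, 0.46 for thrS, 0.43 for htr18 and 0.37 for htr8. It was -0.41 for speB, -0.39 for purF, -0.37 for hisF, -0.36 for orc8 and -0.33 for thiL. With 1 sample per condition these values have no test, and over all probes those of the 2 dye orientations correlated at -0.37. Of these 10 values, 3 turned sign with 1 array left out, namely hisF (0.06 without high oxygen light replicate 2), speB (0.08 without low oxygen dark replicate 2) and thiL (0.00 without low oxygen dark replicate 1). Other processing turned 6, among them hutI (-0.38 with the authors' values) and htr18 (-0.06 without background correction), while phoU lay between 0.47 and 0.80 with an array left out. Of all probes, 37 were at least 2-fold in the positive and 10 in the negative direction with the same sign in both dye orientations, and 0 of them were named. The split was 0 and 40 without background correction, 22 and 15 with median centring and 25 and 15 with scaling between arrays. It was 2 and 6 without the dimmest 25% of probes, 2 and 4 with the authors' values and 0 and 4 in the dimmer scan. Without low oxygen dark replicate 2 it was 40 and 82, but there the rule of one sign in both orientations could not be applied.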

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

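The tests in this part were chosen after these or closely related values were seen. For thrS, the threonyl-tRNA synthetase gene, the light minus dark difference was 0.34 in high oxygen and -0.13 in low oxygen, opposite in sign on both dye orientations, a difference of 0.46. For orc8 it was -0.30 and 0.06, a difference of -0.36. Neither difference was tested. Opposite light differences on both dye orientations were seen in 15 of the 133 named genes, against 16.6 expected if all signs were independent. The pattern was thus no more common than under independent signs. The light differences in high and low oxygen correlated at 0.55 over the named genes, so their signs were not independent. The comparison therefore cannot decide whether the pattern exceeds chance. In the dimmer scan the difference was -0.08 for thrS, and without background correction it was 0.06 for orc8.

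The arrays grouped by dye orientation. Same-orientation arrays of different samples correlated by 0.253 more than opposite-orientation arrays of different samples, which a gene-specific dye bias could produce. A wrong dye label on a single array stays open. The mean correlation with the other arrays of its orientation was below 0 for 0 of the 8 arrays. That cannot decide, because ratios were turned by the label, so a dye bias could keep this correlation positive under a wrong label. The 2 arrays of a sample correlated at -0.14 in low oxygen light and -0.21 in low oxygen dark, which a wrong label or a dye bias could produce. No biological explanation was tested, because the orientation is no group of the design.

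The light minus dark differences in high and low oxygen, which by the labels share no sample, correlated at 0.56 over all probes. The correlation was 0.388 between the upper and lower parts of the slide and 0.39 within a part. That argues against a position effect that differs between the parts as the whole cause. A probe lies at the same place within each part, so a position effect shared by both parts stays open. The correlation needed low oxygen dark replicate 2, being -0.0771 without that array and 0.43 to 0.62 without any other, as a single array could produce. That array enters the low oxygen difference only, so it could do this only through something shared with the high oxygen arrays. A wrong sample label on it, left open below, could make both differences share a sample. Low signal could also contribute, since the correlation was 0.264 in the brightest 25% of probes, below the bound of 0.28 set for that test by less than its standard error of 0.04. A response to light stays open as well, untested with 1 culture per condition.

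Low oxygen dark replicate 2 correlated at 0.42 and 0.50 with replicates 1 and 2 of the high oxygen dark sample and at -0.21 with its own dye-flip partner. Its highest correlation with an opposite-dye array of another sample exceeded that with its partner by 0.634, as a wrong sample label on that array could produce. In the brightest 25% of probes the correlation was 0.713 with high oxygen dark replicate 2, which argues against low signal for that resemblance, though the arrays share a dye orientation. It was 0.123 with replicate 1, of the opposite orientation, so low signal stays open there, and -0.35 with its partner. A response to darkness is also open, untested, and the partner array did not resemble this one.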

How the results depend on the processing

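These results depended on which arrays were used and on the processing. Leaving out the dimmest 25% of probes gave 0 calls for oxygen and 0 for light. As the main counts were also 0, this cannot show whether low signal limited them. Of the alternatives, the dimmer scan, the median of a spot's pixels, lists without pyrF, gdhA1, gdhA2 or bat, and fry under other settings were added after seeing the data. For oxygen, the number of probes called was 0 throughout except 2 in the dimmer scan, and 0 to 1 with an array or sample left out. For light, it was 181 in the dimmer scan, 2 with the authors' values, 525 with all 8 arrays and a random block on the sample, and 0 to 168 with an array or sample left out. The random block had an estimated correlation of -0.67 between the arrays of a sample, which by construction narrows the error of their mean. Of the named genes it called 10 lower in light, among them tmk, also called without high oxygen light replicate 2. It called 1 higher, pyrF, which is labelled as deleted in every sample. With dye orientation as a replicate block, 0 probes were called for oxygen and 0 for light, and the block changed no list call. That fit took the 2 arrays of a sample as separate replicates, so it is no check at the level of samples. Without high oxygen light replicate 2 and in the dimmer scan, 14 higher and 39 lower light calls were shared (1.74 and 3.97 expected of unrelated lists; the slides are the same). camera called 0 of the fixed lists under each alternative it was run with. fry's one-way test, run on 8 left-out arrays and 7 processing settings, called the citrate cycle for oxygen with scaling and without high oxygen dark replicate 2. It called chaperones and proteasome for light in Alexa 532 only (adjusted p = 0.0488). Its test for change in either direction called phototrophy for light on the main values only, and 1 other list each without high oxygen dark replicate 2 (transducers), with median centring (purine and pyrimidine synthesis) and with scaling (DNA repair).

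Probes 2-fold changed by oxygen in both pairs numbered 4 with the sample in Alexa 532 only, 13 in Alexa 647 only, 6 at a threshold of 0.58, and 0 to 4 with an array left out. For light, the count of 8 became 0 without background correction, 0 with the authors' values, 0 without the dimmest 25% of probes, 0 in the dimmer scan, 2 in Alexa 532 only, 41 in Alexa 647 only, 120 at 0.58, and 0 to 17 with an array left out. The difference of differences counted 47 probes with one sign in both dye orientations. This count became 6 with the authors' values, 8 without the dimmest 25%, 4 in the dimmer scan and 179 at 0.58. With a single orientation or an array left out, the sign rule could not be applied. The counts were then 221 in Alexa 532 only, 393 in Alexa 647 only and 68 to 257 with an array left out. They follow a looser rule and cannot be set against the 47. The 1 probe 2-fold from the reference became 0 without background correction, 0 with scaling, 0 with the authors' values, 0 in Alexa 532 only, 0 in the dimmer scan, 2 at 0.58, and 0 to 1 with an array left out. The pyrF ratio was -0.30 without background correction, -0.18 with the authors' values and -0.17 in the dimmer scan; it was among the dimmest 25%. Beyond the left-out arrays and the random block, the cause was not tested. Of 50 named gene values, 16 had the opposite sign with the authors' values, 7 in the dimmer scan and 6 without background correction.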

Other observations

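The tests and gene lists in this part were chosen after the values were seen. Against the reference, 10 of the 133 named genes had one sign on all 8 arrays. Higher in the samples were arcC at 0.35 ± 0.16 (SD, n = 4 samples), the argininosuccinate lyase gene argH at 0.24 ± 0.18 and htr6 at 0.15 ± 0.11. Lower were rpmC at -0.38 ± 0.04, carB of carbamoyl phosphate synthesis at -0.34 ± 0.05, cbiT of cobalamin synthesis at -0.33 ± 0.06, the gyrase gene gyrB at -0.28 ± 0.13, hisI at -0.25 ± 0.09, the citrate synthase gene citZ at -0.25 ± 0.03 and infB at -0.16 ± 0.05. Over all probes, 88 were above and 70 below the reference on every array. No chance value is given, since all arrays share the reference RNA, pairs share a sample and same-dye arrays resemble each other; these values describe the samples against that reference and do not separate the deleted genes from the growth of the reference.

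Of 6 further lists, the 12 aminoacyl-tRNA synthetase genes had 11 members on the low side in high oxygen, from alaS at -0.03 to glyS at -0.29 with ileS at 0.10 (camera adjusted p = 0.0330 over the 6 lists; 0.785 with an estimated correlation; fry 0.261). The adjusted p was 0.0289 to 0.410 with an array left out, the highest being without low oxygen dark replicate 2, where 7 were on the low side. It did not pass under any of the 7 other processing settings, the lowest value being 0.0573 with scaling, and 5 were on the high side with the authors' values. The 4 arginine metabolism genes were all on the high side, in high oxygen (argH at 0.25, arcA at 0.06; adjusted p = 0.0451, and 0.785 with an estimated correlation) and in light (speB at 0.25, arcA at 0.06; adjusted p = 0.0456, and 0.668 with an estimated correlation). These calls depended on single arrays and on the processing. Without high oxygen light replicate 2, 2 of the 4 were on the high side in each comparison (adjusted p = 0.681 for oxygen and 0.344 for light), with argH at 0.02 and arcC at -0.02 for oxygen and argH at -0.06 for light. Without low oxygen dark replicate 2, speB was at -0.12 for oxygen and 0.01 for light. The adjusted p was 0.0874 to 0.681 for oxygen and 0.0312 to 0.344 for light with an array left out. For oxygen the list passed under 1 of the 7 processing settings, without background correction (0.0390), and turned to the low side in the dimmer scan (2 of 4 high, 0.805). For light it passed under 3, and had 2 of 4 on the high side with the authors' values (0.975) and in Alexa 532 only (0.514). The lists were drawn up with these values known, so their p-values are not independent evidence. For oxygen the adjusted p was 0.330 for thiamine synthesis and 0.701 for histidine synthesis, histidine degradation and pyrimidine synthesis. With the authors' values histidine degradation passed for oxygen (0.00701, 0 of 3 on the high side, against 2 of 3 in the main values). For light it was 0.136 for histidine degradation (0.00151 to 0.185 with an array left out, and passing under 3 of the 7 processing settings; its 3 genes were on the low side, but on the high side with the authors' values), 0.341 for thiamine synthesis, pyrimidine synthesis and the synthetases, and 0.961 for histidine synthesis. Adjusted over the list alone, hutG passed for light (limma adjusted p = 0.0464 over 3 genes). It ran from 0.00901 to 0.385 with each array left out and was 0.609 with the authors' values.

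The 1 unnamed probe that was at least 2-fold below the reference in every condition was below it on all 8 arrays, at -1.55 ± 0.37 (SD, n = 4 samples), with a spot to background ratio of 1.32 in the sample channel and 2.52 in the reference channel. The labels name a pair of deleted genes; which gene this probe measures was not known here, and it was singled out after its values were seen.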
